A study of Mus musculus with 4 samples.

How the data were processed

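RNA was measured in testes of male C57BL/6 mice kept on a western diet for 18 weeks, in 2 libraries from wild-type mice (WT) and 2 libraries from mice lacking Tas1r3 (KO). Per the labels' protocols, total RNA was extracted with an RNAqueous kit and sequencing libraries were built with the Ion Total RNA-Seq Kit. The submitters' processing notes name STAR, a spliced aligner, the Partek software and the mouse build mm39. The notes give neither versions nor the role of each tool. Samples were grouped by the genotype in their labels, and the replicate number was taken from the sample titles. Nothing in the labels says that the 2 libraries of a genotype came from separate animals, so p-values measure the spread between these samples, which may be technical.

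The authors deposited 1 table per library with a value for each of the same 29342 RefSeq transcripts, with coordinates on mm39. Each deposited column sums to 1000000 over the listed transcripts. From this the unit was inferred to be CPM (counts per 1000000 assigned reads). The commonest low values were multiples of a step that differed between libraries and equals the CPM of 1 read. That step was 0.582 and 0.553 CPM in WT replicates 1 and 2, and 1.34 and 1.67 CPM in KO replicates 1 and 2. It corresponds to an estimated 1719329 and 1807651 assigned reads in WT and 748634 and 597938 in KO, a mean WT depth 2.62 times the mean KO depth. Other values were fractions of the step, as software that divides a read among transcripts gives. Within a tolerance of 0.01 reads, only 20.6% to 49.0% of genes per library had a whole number of reads, so read counts were not reconstructed and no count model was fitted. Estimated reads are CPM divided by the step. The tables hold 0 mitochondrial transcripts. At 0 CPM stood 47 and 95 genes in the WT libraries and 792 and 890 in the KO libraries. Whether transcripts were filtered before deposit is not given in the sources used here.

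Transcript values were summed per gene symbol, with 10 symbols found on several chromosomes kept apart by chromosome, which gave 17934 genes. The 17654 genes with a mean of at least 1 CPM over the 4 libraries were tested. The values of 159 tested genes equal those of another gene in every library. KO was compared with WT by limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with a mean-variance trend and a two-sided moderated test. P-values were adjusted by the Benjamini-Hochberg method (BH) over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(CPM + 1) scale, KO minus WT, and understate the change of low genes. Where a ratio of mean CPM is given, it is named as a fold. For a gene with 0 estimated reads in a genotype, the fold is a lower bound computed against 3 reads over both libraries of that genotype. This bound takes the reads of the other genotype as measured, so the 95% exact lower limit lies below it. With 1 to 3 reads, the ratio of summed reads scaled by depth is given with its 95% exact conditional interval. Intervals and floors pool the reads of both libraries of a genotype and cover counting error only, not the spread between libraries. Such an interval is therefore no test of genotype. Every read is counted, since reads carry no molecular identifiers.

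Gene lists, named genes, the test and its alternatives, apart from those named below as added, were chosen before the data were examined. Count models were planned only for the case that whole reads could be recovered, and were not run. The 27 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, BH-adjusted over the lists. The list of mitochondrially encoded genes had 0 of 15 members measured and was not tested. The named genes were Tas1r3, up to 12 called genes per direction by size of change, and, because fewer than 5 genes were called per direction, the genes with the smallest unadjusted p and non-overlapping genotypes up to 10 per direction. To these came up to 4 members of each list with the smallest unadjusted p. Predicted genes were not named. Of the list members chosen by this rule, some are described only through their list.

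The alternatives were pseudocounts of 0.1 and 5 CPM, no filter, a mean of at least 5 CPM, trimmed mean of M values (TMM) factors computed on the deposited values, quantile normalization, no mean-variance trend, the replicate number as a block, an adjusted p under 0.1, an added minimum log2 change of 1, and each library left out. For lists, camera with an estimated correlation, camera on ranks and limma's fry were also run. Thinning of estimated reads to the shallowest library, and removal of the 18S ribosomal RNA gene Rn18s, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.

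The procedure was tested on simulated libraries of 17345 genes with the depths of the 4 libraries and a scatter of 10.8% beyond counting error. This scatter was taken from genes of 100 CPM or more and was the same for every gene. The shares called therefore do not hold for genes that scatter more. For KO against WT, it called 47.2% of 2-fold, 86.0% of 4-fold and 100% of 8-fold changed genes at 10 CPM or more. Below 10 CPM it called 0%, 29.2% and 32.0%, and 1 unchanged gene was called. In the deposited data, the median 95% confidence interval of a fold change reached 1.28-fold to either side at 100 CPM or more. It reached 1.70-fold at 10 to 30 CPM and 3.39-fold at 1 to 3 CPM.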

Results

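Testis RNA was sequenced from mice homozygous for a null allele of Tas1r3 and from Tas1r3 wild-type mice, all fed a western diet for 18 weeks. Tas1r3 encodes a subunit shared by the sweet and umami taste receptors. The comparison of 2 KO with 2 WT libraries asks which testicular transcripts differ when this subunit is missing under that diet. The estimated depth was 1719329 and 1807651 assigned reads in the WT libraries and 748634 and 597938 in the KO libraries, so depth differed between the genotypes.

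Tas1r3 was low in both KO libraries. The gene, at chromosome 4, 155943726 to 155947811 on the minus strand of mm39, had 13.8 and 20.5 CPM in WT and 1.34 and 0 CPM in KO. This corresponds to 61 estimated reads in WT and 1 in KO, a KO level of 4.29% of WT with a 95% exact conditional interval from 0.11% to 24.8%. Its log2 fold change was -3.54 (SE 0.61), and it did not pass the test over all genes (limma, BH-adjusted p = 0.627). With a library left out, the BH-adjusted p by limma was 1 without WT replicate 1 or WT replicate 2, 1.31e-07 without KO replicate 1 and 2.03e-05 without KO replicate 2. The last 2 fits take their spread from the WT pair alone and call 954 and 413 genes.

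**Figure D1:**
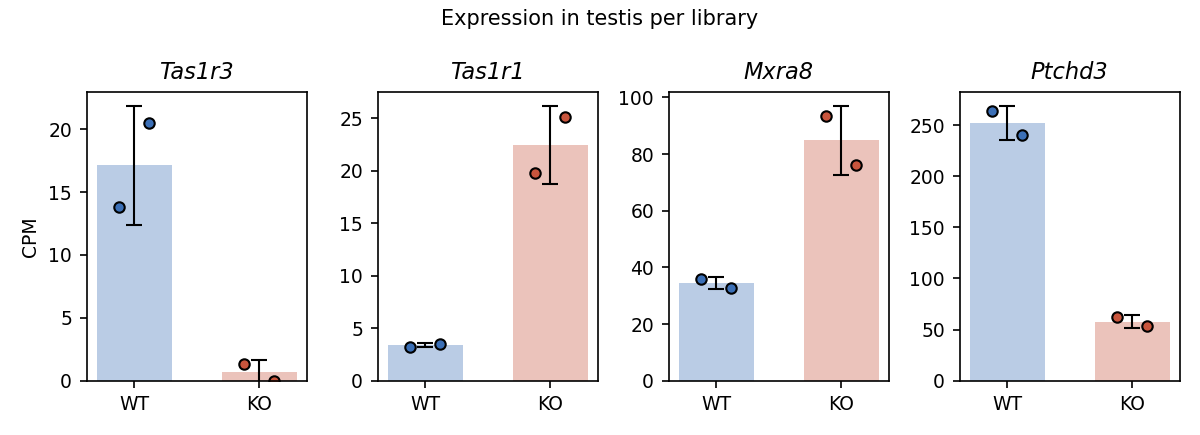
CPM of Tas1r3, Tas1r1, Mxra8 and Ptchd3 in testis, each on its own axis, with points for the 2 libraries per genotype, bars for their mean and error bars for the SD (n = 2). The WT and KO libraries do not overlap for any of the 4 genes, and Ptchd3 alone passed the test over all genes.

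Ptchd3 fell in KO testis. This gene encodes a patched domain protein of male germ cells and lies at chromosome 11, 121721044 to 121734263. It had 252 ± 16.6 CPM in WT and 57.7 ± 6.21 CPM in KO (SD, n = 2), a 4.37-fold lower mean, and a log2 fold change of -2.11 (SE 0.16; limma, BH-adjusted p = 0.00763). Ptchd3 was the only gene called among 17654 tested, with 0 genes higher and 1 lower. At an unadjusted p under 0.05 there were 765 genes, 234 higher and 531 lower in KO, where 883 would be expected by chance. After quantile normalization that split was 344 higher and 418 lower, and with TMM factors it was 232 higher and 542 lower. The genotypes did not overlap for 34.3% of genes, against 33.3% by chance. The Ptchd3 call was lost with a pseudocount of 0.1 CPM (limma, BH-adjusted p = 0.0729), without the mean-variance trend (0.247), after thinning to equal depth (0.839), and without WT replicate 1 or WT replicate 2 (1 in each). Its log2 fold change stayed between -2.22 and -2.004 in every alternative.

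**Figure D2:**
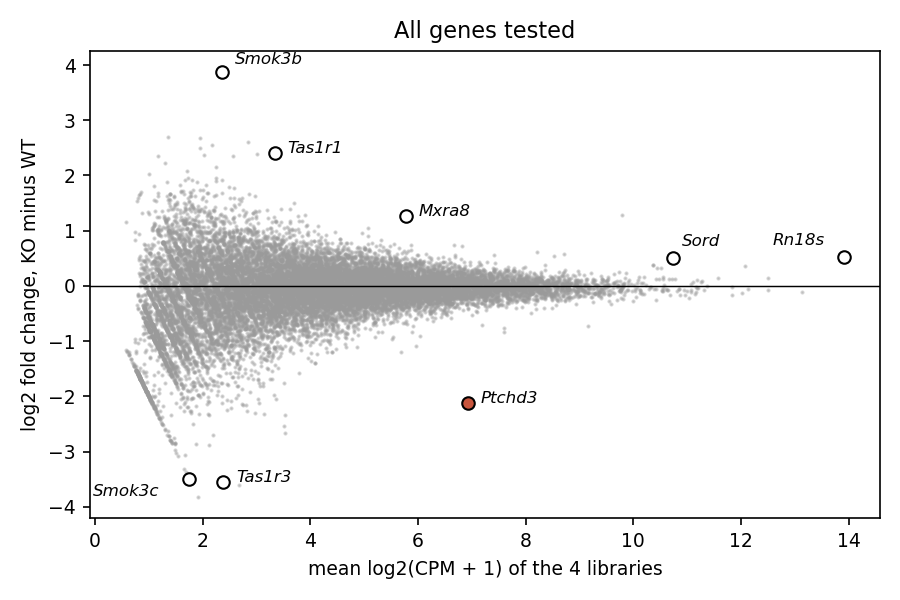
Log2 fold change (KO minus WT) against mean log2(CPM + 1) for the 17654 genes tested, 1 point per gene, with the called gene filled in red and other named genes as open circles. Ptchd3 stands at -2.11 in the well-measured range, while the scatter widens toward low expression, where 1 read moves a gene most.

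The genes closest to the threshold on the higher side included the umami receptor subunit gene Tas1r1 and Mxra8, which encodes a cell-surface adhesion protein and lies near Tas1r3. Tas1r1, at chromosome 4, 152112371 to 152122948, had 3.38 ± 0.206 CPM in WT and 22.4 ± 3.74 CPM in KO (SD, n = 2), a 6.65-fold higher mean. It had 5.6 and 6.4 estimated reads in WT replicates 1 and 2 and 14.8 and 15 in KO replicates 1 and 2. With so few reads, an SD of 2 libraries can lie below counting error. Mxra8 had 34.5 ± 2.23 CPM in WT and 84.9 ± 12.2 CPM in KO, a 2.46-fold higher mean. Sord, encoding sorbitol dehydrogenase, had 1436 ± 11.4 CPM in WT and 2036 ± 126 CPM in KO. Vamp3, a vesicle fusion gene, had 44.1 ± 1.70 and 75.0 ± 9.13 CPM, and the serine protease gene Prss47 had 11.1 ± 1.60 and 24.7 ± 2.86 CPM. Mblac2 had 2.28 ± 0.883 and 10.2 ± 2.61 CPM. Psme2b, a near copy of the proteasome activator gene Psme2, had 5.88 ± 1.44 and 16.9 ± 0.246 CPM, and reads can be divided between such copies. Setdb2, a SET domain gene, had 0 estimated reads in WT and 8 in KO, at least 6.59-fold higher against the floor of 3 reads, with a 95% exact lower limit of 4.47. Rn18s, the 18S ribosomal RNA, took 1.39% and 1.19% of the WT libraries and 1.93% and 1.76% of the KO libraries. None of these genes passed (limma, BH-adjusted p from 0.627 to 0.95).

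On the lower side, next to Ptchd3 and Tas1r3, stood Gsdma, a pore-forming gasdermin gene, with 16.3 ± 2.35 CPM in WT and 3.01 ± 0.476 CPM in KO (SD, n = 2). Eif4ebp2, encoding a repressor of cap-dependent translation, had 20.1 ± 2.83 and 5.33 ± 1.91 CPM. The others had at most 1 estimated read in KO. Sall4, a transcription factor gene of spermatogonia, had 34 estimated reads in WT and 0 in KO, at least 4.29-fold lower. Trmt61a, a transfer RNA methyltransferase gene, was at least 2.96-fold lower. Tmed5, of the secretory pathway, had 38 reads in WT and 1 in KO, a ratio of 14.5 with a 95% exact interval from 2.45 to 588. Ipo11-lrrc70 is a readthrough gene and Pcdhgb1 belongs to a cluster with shared exons, so their values are uncertain (at least 4.12-fold and 3.13-fold lower). None of these genes passed (limma, BH-adjusted p = 0.95). Smok3b and Smok3c, near-identical kinase genes on chromosome 5, lay on opposite sides: Smok3b had 1 estimated read in WT and 25 in KO, a KO to WT ratio of 65.5 (95% exact interval 10.7 to 2690). Smok3c had 37 in WT and 0 in KO, at least 4.69-fold lower. Neither passed (limma, BH-adjusted p = 0.441 and 0.778), and their sum with Smok3a was 23.5 and 30.6 CPM in WT and 18.8 and 47.3 CPM in KO.

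Among taste receptor signalling genes, 0 of 10 measured members passed over all genes tested, and 2 passed adjusted over the list alone. These were Tas1r1, higher in KO, and Tas1r3, lower (limma, BH, adjusted p = 0.00124 for both over the list alone). Tas1r3 is the targeted gene, so its passing says nothing about the rest of the list. Itpr3, the calcium release channel of taste cells, had 33.3 ± 7.93 CPM in WT and 28.7 ± 1.98 CPM in KO, and the cation channel gene Trpm4 had 45.1 ± 6.72 and 50.1 ± 4.72 CPM (SD, n = 2). Of 23 measured genes flanking Tas1r3 on distal chromosome 4, 0 passed over all genes and 1 passed adjusted over the list alone, Mxra8 (limma, BH, adjusted p = 0.00375 over the list alone). Ints11, an Integrator complex gene near Tas1r3, had 36.4 ± 6.96 CPM in WT and 16.5 ± 4.40 CPM in KO (limma, BH, adjusted p = 0.0554 over the list alone). Ccnl2, a cyclin gene, had 42.5 ± 4.78 and 28.4 ± 2.15 CPM, and the lipid transfer gene Cptp had 185 ± 3.49 and 225 ± 8.79 CPM. Neither list stood apart as a set by camera (limma, BH-adjusted p = 0.978 for taste and 0.962 for flanking genes).

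**Figure D3:**
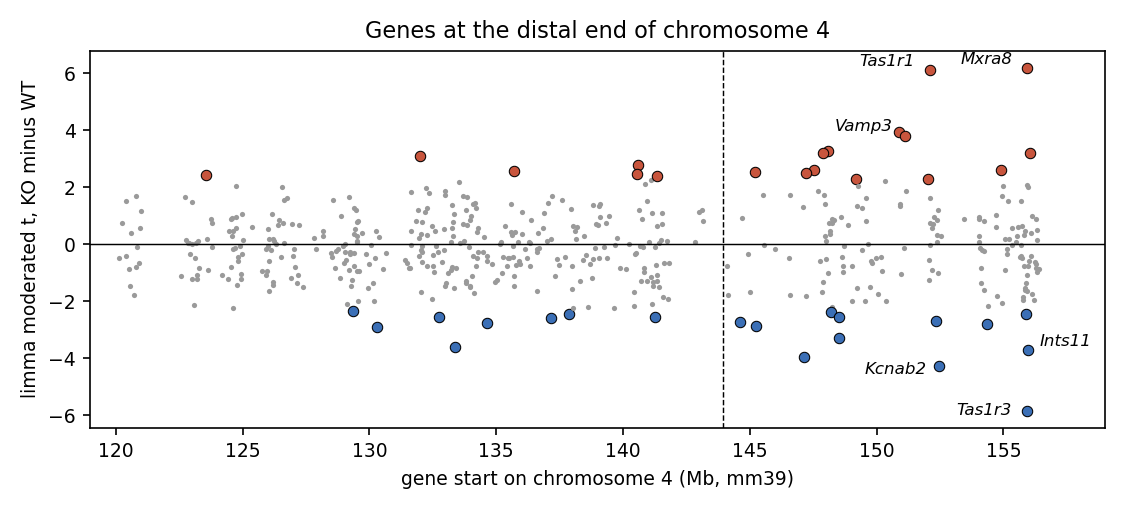
Moderated t of KO against WT from limma for each tested gene by its start on chromosome 4 from 120 Mb to the end (mm39), with genes at an unadjusted p under 0.05 in red (higher in KO) or blue (lower) and the dashed line 12 Mb from Tas1r3. Tas1r3 is the lowest point and Tas1r1 and Mxra8 the highest, and red and blue points are both present to the right of the line.

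Red blood cell transcripts were lower in KO as a list, most of all against WT replicate 2, and the call did not hold in every setting. The list was the only one of 27 called by camera, with a median log2 fold change of -0.99 over 6 measured members (limma camera, BH-adjusted p = 0.0375; adjusted p = 0.987 with an estimated correlation). The members sum to 52.97 and 188 CPM in WT replicates 1 and 2 and to 35.8 and 59.2 CPM in KO. Without WT replicate 2 the median was -0.27 and the list was not called (limma camera, BH-adjusted p = 0.966), and without WT replicate 1 it was -2.12 (1.59e-05). The list was also not called without KO replicate 1 (median -0.69, adjusted p = 0.699) or KO replicate 2 (-1.48, 0.0847), nor after thinning to equal depth (-0.93, 0.358), by limma camera with BH. Over all genes, 0 members passed. Adjusted over the list alone, 1 passed, the beta globin gene Hbb-bt, with 24 estimated reads in WT and 0 in KO, at least 3.03-fold lower (limma, BH, adjusted p = 0.0153 over the list alone). Hbb-bs, a near-identical beta globin gene, had 4.98 and 31.2 CPM in WT and 3.74 and 6.97 CPM in KO. Hba-a2, an alpha globin gene, had 9.14 and 66.5 CPM in WT and 8.84 and 15.2 CPM in KO, and Alas2, of erythroid haem synthesis, had 16.8 ± 1.25 and 10.4 ± 0.461 CPM.

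**Figure D4:**
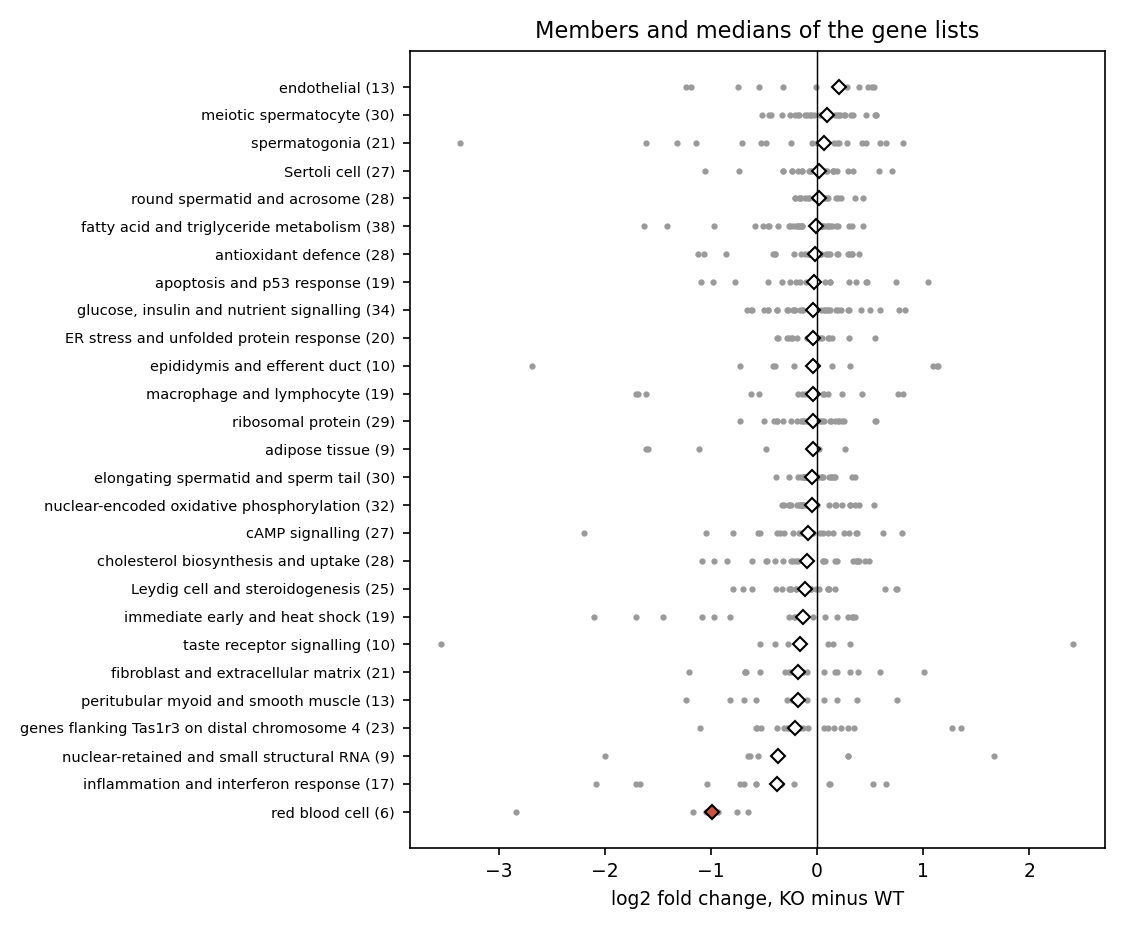
Log2 fold change (KO minus WT) of the measured members of the 27 tested lists (grey points, number measured in brackets), with the list median as a diamond, filled in red where camera called the list. The red blood cell list has the lowest median, -0.99, and most other medians lie close to 0.

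No member of the germ cell lists passed over all genes tested. The spermatogonia list had 0 of 21 measured members called over all genes and 1 adjusted over the list alone, Sall4 (limma, BH, adjusted p = 0.0122 over the list alone). Of its 21 members, 12 had a higher and 9 a lower mean log2 value in KO. The transcription factor gene Pou5f1 had 8.99 and 6.2002 CPM in WT and 0 and 6.69 CPM in KO. Dmrt1 had 20.1 ± 5.31 CPM in WT and 31.9 ± 7.39 CPM in KO, and Uchl1 had 48.3 ± 2.03 and 65.2 ± 7.17 CPM (SD, n = 2). The list's median log2 fold change was 0.06 and its mean -0.26. Of 30 meiotic spermatocyte genes, 0 passed over all genes and 0 passed adjusted over the list alone, as held for 28 round spermatid and acrosome genes and 30 elongating spermatid and sperm tail genes. Hormad1 and Sycp1, of the meiotic chromosome axis and the synaptonemal complex, had 51.4 ± 6.21 and 55.4 ± 2.72 CPM in WT and 75.7 ± 0.622 and 76.4 ± 2.08 CPM in KO. Spaca1 and Izumo1, of the acrosome and of sperm-egg fusion, had 134 ± 8.87 and 94.9 ± 6.67 CPM in WT and 181 ± 2.34 and 122 ± 14.2 CPM in KO. The sperm tail gene Odf3 had 257 ± 10.6 and 196 ± 6.84 CPM, and the transition protein gene Tnp2 had 4097 and 3549 CPM in WT and 3644 and 6571 CPM in KO. Camera called none of the 4 germ cell lists (limma, BH-adjusted p from 0.699 to 0.978).

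Steroidogenic and lipid genes did not pass. In the Leydig cell and steroidogenesis list 0 of 25 measured members passed, over all genes or adjusted over the list alone. Insl3, the Leydig cell hormone, had 1491 ± 37.5 CPM in WT and 1256 ± 31.4 CPM in KO, and the glutathione transferase gene Gstm1 had 413 ± 16.3 and 318 ± 64.6 CPM (SD, n = 2). Cyb5a, a cofactor of androgen synthesis, had 21.5 ± 4.83 and 12.7 ± 0.960 CPM. Cyp17a1, the 17-hydroxylase and lyase of that pathway, had 46.5 and 129 CPM in WT and 135 and 127 CPM in KO. In the cholesterol biosynthesis and uptake list 0 of 28 members passed in either way. There Pmvk, encoding phosphomevalonate kinase, had 17.2 ± 2.998 and 8.29 ± 1.503 CPM, and Hmgcs1, of the same pathway, 34.3 ± 3.33 and 45.1 ± 9.05 CPM. In the fatty acid and triglyceride metabolism list 0 of 38 passed in either way. Its fatty acid binding protein gene Fabp3 had 85.7 ± 10.3 and 63.5 ± 17.8 CPM, and Fabp5 had 17 estimated reads in WT and 1 in KO, a ratio of 6.49 (95% exact interval 1.02 to 271). Camera called none of these 3 lists (limma, BH-adjusted p = 0.962 each).

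Lists of supporting, vascular and immune cells held 0 members that passed, over all genes or adjusted over the list alone. They covered 27 Sertoli cell, 13 peritubular myoid and smooth muscle, 21 fibroblast and extracellular matrix, 13 endothelial, 19 macrophage and lymphocyte and 17 inflammation and interferon response genes. The Sertoli cell genes Trf, for transferrin, and Inha, for inhibin alpha, had 26.7 ± 2.05 and 101 ± 3.29 CPM in WT and 17.0 ± 9.91 and 86.1 ± 10.5 CPM in KO (SD, n = 2). Ocln, of tight junctions, and the homeobox gene Rhox5 had 4.78 ± 1.06 and 8.53 ± 1.10 CPM in WT and 8.33 ± 0.348 and 13.7 ± 5.18 CPM in KO. The Sertoli cell list had 15 members higher and 12 lower. The smooth muscle genes Smtn and Tagln had 10.9 ± 2.85 and 13.8 ± 1.51 CPM in WT and 3.95 ± 0.00291 and 7.35 ± 0.937 CPM in KO. Smtn had only 3 and 2.4 estimated reads in KO replicates 1 and 2, so its small SD there is no sign of precision. Sox17 and Flt1, of endothelium, had 25.7 ± 0.870 and 13.3 ± 2.31 CPM in WT and 11.03 ± 5.71 and 5.37 ± 1.87 CPM in KO, while the endothelial claudin gene Cldn5 had 9.87 ± 4.71 and 14.1 ± 2.75 CPM. The endothelial list had 7 members higher and 6 lower, with a median log2 fold change of 0.20 and a mean of -0.11. Igfbp3, of the fibroblast list, had 3.43 ± 0.932 and 8.26 ± 4.12 CPM. The collagen gene Col6a1 had 16.0 ± 4.23 and 7.24 ± 5.51 CPM, and the macrophage complement gene C1qb 15.7 ± 0.786 and 10.4 ± 0.573 CPM. Tyrobp, of myeloid cells, had 8 estimated reads in WT and 0 in KO, a difference not detectable at this depth. Inflammation and interferon response had the lowest median of these lists, -0.38, with 13 of 17 members lower (limma camera, BH-adjusted p = 0.461). Its member Irf1 had 28 estimated reads in WT and 2 in KO, a ratio of 5.35 (95% exact interval 1.35 to 46.3). Oasl2 had 15 and 1, a ratio of 5.73 whose interval, 0.881 to 241, includes no difference. The other 5 lists had BH-adjusted p from 0.698 to 0.962 by limma camera.

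Metabolic, stress and signalling lists had 0 members passing as well, over all genes or adjusted over the list alone. They were antioxidant defence (28 measured), ER stress and unfolded protein response (20), nuclear-encoded oxidative phosphorylation (32), cAMP signalling (27) and glucose, insulin and nutrient signalling (34). Further lists were immediate early and heat shock (19), apoptosis and p53 response (19), ribosomal protein (29) and nuclear-retained and small structural RNA (9). Sesn1, a stress-responsive regulator of nutrient signalling, had 18.4 ± 0.335 CPM in WT and 32.3 ± 5.53 CPM in KO, and Insr, the insulin receptor gene, 12.9 ± 4.38 and 23.2 ± 2.59 CPM (SD, n = 2). Mtor, the nutrient-sensing kinase gene, had 277 ± 8.52 and 213 ± 31.0 CPM. Rapgef3, a cAMP-activated exchange factor gene, had 16.2 ± 0.974 and 8.90 ± 0.754 CPM, and the phosphodiesterase gene Pde4c had 22 estimated reads in WT and 1 in KO, a ratio of 8.40 (95% exact interval 1.36 to 347). The immediate early gene Jun had 16.1 ± 3.86 CPM in WT and 7.72 ± 1.94 CPM in KO, and Egr1 had 29 estimated reads in WT and 2 in KO, a ratio of 5.54 (95% exact interval 1.40 to 47.9). Gadd45a and Gadd45b, of the DNA damage response, differed in sign: 3.92 ± 0.213 and 9.27 ± 1.72 CPM in WT, and 9.22 ± 1.38 and 3.79 ± 0.311 CPM in KO. The peroxidase genes Gpx3 and Prdx1 had 23.5 ± 12.3 and 53.1 ± 3.09 CPM in WT and 10.03 ± 1.59 and 69.8 ± 0.571 CPM in KO. Neat1, a nuclear-retained RNA, had 67.6 ± 8.98 and 43.1 ± 6.17 CPM. The ribosomal protein genes Rpl37 and Rps14 had 75.8 ± 4.63 and 304 ± 33.6 CPM in WT and 46.3 ± 12.5 and 455 ± 143.5 CPM in KO. The chaperone gene Dnajb9 had 65.6 ± 2.38 and 81.3 ± 10.9 CPM. Camera called none of these 9 lists (limma, BH-adjusted p from 0.698 to 0.978).

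Markers of neighbouring tissues did not separate the genotypes. In the epididymis and efferent duct list 0 of 10 measured members passed, and in the adipose tissue list 0 of 9, over all genes or adjusted over the list alone (limma camera, BH-adjusted p = 0.760 and 0.699). Across genes, the Pearson correlation of log2(CPM + 1) was 0.963 between the WT libraries, 0.910 between the KO libraries and 0.928 to 0.941 between the genotypes. Genes are not independent replicates. The first principal component took 48.0% of the variance and parted the KO libraries from each other, at -48.6 and 72.0. The second took 34.3% and placed WT at 38.5 and 33.6 and KO at -50.0 and -22.0. As a check for a library deposited under both numbers, the estimated reads of libraries of a genotype were compared: the chi-square per gene had a mean of 1.82 and a median of 0.656 in WT, and a mean of 3.09 and a median of 0.945 in KO. All 4 libraries were kept as separate samples.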

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

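Thinning to equal depth and removal of Rn18s were chosen after seeing the data. Of 1175 values for 85 named genes beyond Tas1r3 under the alternatives, 1093 kept their direction and side of the threshold and 63 came past it. Another 5, all for Ptchd3 among its 14 settings, no longer passed. Apart from Ptchd3 none of these genes was called at first, so keeping the side means staying uncalled for them. The gene count was 1, but 0 with a pseudocount of 0.1 CPM, 0 without the mean-variance trend and 0 after thinning, and it ranged from 0 to 954 with a library left out (0 without either WT replicate, 954 without KO replicate 1, 413 without KO replicate 2). The lone library of a genotype was then assumed to vary like the other pair. Without a KO library the spread came from the WT pair, which differs least. With the replicate number as a block the count was 24, 6 higher and 18 lower, including Ptchd3 and Tas1r3 (log2 fold change -3.54; limma, BH-adjusted p = 0.000277). Same-numbered libraries did not deviate together (r = -0.0059 over 17654 genes). With 2 pairs this cannot exclude pairing, and the labels do not say that equal numbers pair animals. The log2 fold change of Tas1r3 depended most on the pseudocount, with -5.48 at 0.1 CPM and -1.96 at 5 CPM, and ranged from -4.16 to -2.93 with a library left out.

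The list count was 1, but 0 with a pseudocount of 0.1 CPM, without a filter, with a mean of at least 5 CPM (where the red blood cell list kept too few members for a test), after thinning, with an estimated correlation, on ranks and by fry's directional test. It ranged from 0 to 1 with a library left out, and without WT replicate 2 the called list was adipose tissue. The mixed test of fry, which asks whether genes change in either direction, called 4 lists: taste receptor signalling, spermatogonia, macrophage and lymphocyte, and immediate early and heat shock (limma fry, BH-adjusted p = 0.0441, 0.00977, 0.00255 and 0.00331). The taste receptor list holds the targeted gene Tas1r3 and was not tested without it. The red blood cell list had a BH-adjusted p by limma camera of 0.0512 with a pseudocount of 0.1 CPM, 0.0523 without a filter, 0.358 after thinning, 0.987 with an estimated correlation and 0.0933 on ranks. With a library left out it ranged from 1.59e-05 to 0.966. The library correlation was 0.922 in WT and 0.802 in KO with a pseudocount of 0.1 CPM.

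Log2 fold changes that reversed, none of them called, were C1qb after thinning (0.27) and Adipoq with a pseudocount of 5 CPM (0.0068), after quantile normalization (0.0306), after thinning (0.57) and without Rn18s (0.0048). With a library left out, Tnp2 ranged from -0.0656 to 0.78, Hbb-bs from -2.39 to 0.0415, Hba-a1 from -1.84 to 0.32, Hba-a2 from -2.42 to 0.32 and Itpr3 from -0.43 to 0.0476. Fabp4 ranged from -2.30 to 0.0738, Smok3a from -1.98 to 0.58 and Adipoq from -0.46 to 0.45. The cause of these changes was not tested, except that fewer samples or reads enter some fits. Planned count models were not run, since whole reads could not be recovered. The KO depth limits genes below 10 CPM most.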

Other observations

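Of the tests here, the one on expression-matched gene sets was set before its result was seen, and the others after. The extent of chromosome 4 it was run on was nonetheless chosen after seeing the data. Genes at the distal end of chromosome 4, the arm that carries Tas1r3, differed between the genotypes more often than other genes. Within 12 Mb of Tas1r3, an extent chosen after seeing the data, 24 of 163 genes other than Tas1r3 had an unadjusted p under 0.05 (14.7%, against 4.23% of 17490 other genes). They include Tas1r1, Mxra8, Ints11, Ccnl2, Vamp3 and Mtor. Others are Zfp933, a zinc finger gene (2.91 and 2.54 CPM in WT, 8.22 and 12.3 CPM in KO), and Clcn6, a chloride transporter gene (9.36 and 9.42 CPM in WT, 18.7 and 23.4 CPM in KO). Kcnab2, a potassium channel subunit gene, had 62.3 and 62.7 CPM in WT and 36.4 and 29.3 CPM in KO. C1qtnf12, encoding an adipokine, had 6.84 and 8.85 CPM in WT and 26.7 and 15.1 CPM in KO. None passed over all genes (limma, BH-adjusted p from 0.627 to 0.95). The share was 7.84% of 51 genes within 1 Mb of Tas1r3, 16.2% of 37 genes at 1 to 4 Mb, 13.7% of 51 genes at 4 to 8 Mb, 29.2% of 24 genes at 8 to 12 Mb, 5.77% of 104 genes at 12 to 20 Mb and 3.38% of 325 genes at 20 to 40 Mb. Of 457 windows of 5 Mb across the genome, those at 145 to 150 Mb and 150 to 155 Mb of chromosome 4 ranked 1 and 2 (11 of 57 and 8 of 52 genes; hypergeometric test, BH-adjusted p = 0.0127 and 0.375). The 11 genes at 145 to 150 Mb include the zinc finger genes Zfp990, Zfp991, Zfp982 and Zfp933. Whether reads were divided between similar genes there was not tested, and the hypergeometric test takes genes as independent. The window that holds Tas1r3, from 155 Mb, ranked 49 (4 of 48 genes; hypergeometric test, BH-adjusted p = 1).

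The expression level and depth of these genes did not account for the excess: 0 of 10000 gene sets matched on mean CPM held as many, and their highest count was 18. The matched sets make no allowance for the choice of the extent. Loss of non-reference reads in alignment as the whole cause was argued against by direction, since 54.2% of the 24 genes (13) were higher in KO (95% exact interval 32.8% to 74.4%), though it stays open for the 11 lower genes. The excess was clustered: 21 of 10000 circular shifts of the gene order gave as large an excess when its extent could be any of 5, and 0 of these lay clear of this end of chromosome 4. A chromosome segment inherited with the Tas1r3 mutation and an effect of losing Tas1r3 on its neighbours could both give such a cluster and cannot be told apart, since segment and mutation come together in this design and no allele data were analysed here. The ratio of the shares, 3.48, ranged from 1.59 (without KO replicate 1 or without KO replicate 2) to 4.95 (mean of at least 5 CPM) and was 2.10 after thinning.

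More genes were lower than higher in KO at an unadjusted p under 0.05 (531 against 234), mostly weakly expressed ones. After quantile normalization the split was 418 lower and 344 higher, but with TMM factors it was 542 lower and 232 higher. The gap therefore depended on the kind of normalization, and rescaling by TMM factors did not narrow it. Genes of 1 to 3 CPM had a median log2 fold change of -0.32 and summed to 0.809 times the WT level, whereas genes of 30 CPM or more summed to 1 times that level. Thinning to equal depth left 53.5% of the excess of lower genes, but by raising the higher count (411) more than the lower one (570), and the median of genes of 1 to 3 CPM was then -0.24, so it does not show that depth produced the lower values. In 5 sets of libraries simulated at these depths without any change, over 17352 genes, the medians were 469 lower and 329 higher, with 0 genes and 1 list called in all. Unequal depth alone thus gave more lower than higher genes in these simulated sets, with a smaller gap than in the data. The shares of depth and genotype in the gap of the data cannot be told apart, because both KO libraries are the shallow ones. A filter applied before deposit was not tested.

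Smok3b was near 0 in WT and Smok3c near 0 in KO. These genes are near-identical neighbours. Reads of the family may have been assigned to different copies in the 2 genotypes, because of a sequence variant or of the assignment itself. The sum with Smok3a had a log2 fold change of 0.15 (95% confidence interval -0.75 to 1.05 from limma) and does not decide it: 18.8 CPM in KO replicate 1 lies below both WT libraries (23.5 and 30.6 CPM) and 47.3 CPM in KO replicate 2 above both. A change of the separate genes stays open.

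The count of 1 called gene was also reached by both other splits of the 4 libraries into pairs, 1 gene each (limma, BH-adjusted), and 4 libraries allow too few splits for a share under 0.05.

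Some libraries held transcripts of other tissues. Crisp1, a gene of the epididymis, had 70 estimated reads (40.7 CPM) in WT replicate 1 and 0 in the other 3 libraries. Of the same list, Adam7 had 5.42 CPM in WT replicate 1 and at most 1.34 CPM elsewhere. Rnase10 went the other way, with 0.0045 CPM in WT replicate 1 and 3.46 to 3.88 CPM elsewhere. The measured epididymis and efferent duct genes summed to 209 and 201 CPM in WT and 171 and 238 CPM in KO. Cidec and Fabp4, of fat cells, had 7.86 and 7.03 CPM in WT replicate 1 and at most 0.586 and 1.67 CPM elsewhere. Adipoq, also of fat cells, had 15.7 and 11.1 CPM in WT and 9.35 and 18.4 CPM in KO, and Plin1 had 3.37 and 2.33 CPM in WT and 5.32 and 1.36 CPM in KO. Hba-a1 had 61.7 CPM in WT replicate 2 and 12.5 to 21.6 CPM elsewhere.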
